A study of Homo sapiens with 9 samples.

How the data were processed

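RNA sequencing of total RNA from LAPC4 cells gave 9 libraries, 3 each from control, knockdown-labelled and rescue cells at day 30. Sequencing was paired-end per the labels' protocols. Per the submitters' processing notes, FastQC, cutadapt, STAR and HTSeq were used with the hg38 build; their versions, settings and annotation are not given in the sources used here. The deposited values are whole-number read counts per gene, not normalized by the authors. Each file held 60325 gene rows and summary rows for reads without a gene. Those summary rows stayed out of library sizes and tests. Of all rows' counts, 43.7% to 48.7% lay on no feature, 2.36% to 3.14% were ambiguous and 7.67% to 11.6% aligned to more than 1 place.

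Whether counting used strand is not given in the sources used here. In 126 pairs of an antisense gene lying inside exons of a well-expressed gene, the antisense gene had a median of 2.75 times the count density of its partner, and the gene antisense to GAPDH held 53.8% to 73.4% of the GAPDH count. Antisense and overlapping genes are therefore uncertain and were not named, but they stay in the counts of genes tested and passed. Gene symbols were matched to GENCODE release 29 on GRCh38 for type, position, length and GC content, and 57032 rows matched one gene.

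Counts were tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood F test, filterByExpr with a minimum count of 10, TMM factors, all 9 libraries in one fit with 6 residual degrees of freedom). A gene passed at a Benjamini-Hochberg adjusted p under 0.05. Standard errors are the log2 fold change divided by the square root of F, and intervals hold 95% confidence. CPM are counts per 1000000 scaled by TMM. Intervals cover the spread between libraries as the fit sees it.

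The 3 comparisons, the tests, 27 gene lists and the rule for named genes were set before the data were examined. The rule took, per comparison, UGT2B28, the 10 protein-coding genes with the largest rise and the 10 with the largest fall among those that passed, had a mean of at least 2 CPM in the higher group and did not overlap between groups, and up to 3 members of each described list with the smallest p. UGT2B paralogs with counts were also named. The lists were tested with camera in limma 3.58.1 on log2 CPM (prior count 2, preset correlation 0.01), beside camera with an estimated correlation and fry, for the 26 lists with at least 5 tested members. Fry asks whether a list's genes move one way on balance and does not compare the list with other genes.

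The fit was tested on simulated counts for each comparison, with 200 genes changed. Of 100 genes changed 2-fold, 45% were recovered for knockdown-labelled against control, 47% for rescue against knockdown-labelled and 55% for rescue against control; of 100 changed 4-fold, 77%, 83% and 78% were. False calls numbered 8 of 130, 12 of 142 and 13 of 146. At 8132206 to 14185252 counts per library a 2-fold change was thus missed in about as many simulated genes as it was found. The real knockdown-labelled libraries did not all resemble each other, as described below. Whether these recovery and false-call rates hold with such a spread within a group was not tested.

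Alternatives set beforehand were DESeq2 1.42.0 size factors, library size alone, no filter on low counts, a filter of 1 CPM in 3 libraries, the DESeq2 Wald test, limma-voom, only the groups compared, the replicate number as a block, stricter thresholds, and each library left out in turn. Sample quality weights in voom, leaving out knockdown libraries 1 and 2 together, and a loess correction for gene length and GC content were added after seeing the data. Of the tested genes, 97.8% had a length and a GC content.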

Results

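Gene expression in LAPC4 cells, an androgen-responsive human prostate cancer line, was measured by RNA sequencing at day 30 of a series on UGT2B28. UGT2B28 encodes a UDP-glucuronosyltransferase, an enzyme of the endoplasmic reticulum that conjugates steroids, androgens included, with glucuronic acid. The 9 libraries fell into 3 groups of 3: control cells, cells labelled as UGT2B28 knockdown, and cells labelled as rescue, in which UGT2B28 was overexpressed on the knockdown background. The labels give 3 ug/mL puromycin as the selection for the knockdown and 1 mg/mL G418 as that for the rescue. The deposited counts summed to 8132206, 9303171 and 9410048 in the control libraries, to 9386058, 14185252 and 8292433 in the knockdown-labelled libraries and to 13983102, 10562751 and 9791044 in the rescue libraries. Nothing in the labels says whether replicates were separate cultures, so p-values measure only the spread between these libraries, which may be technical. The selection drug differs with the label, and none is given for the controls. An effect of puromycin therefore cannot be told from one of the knockdown in the knockdown-labelled libraries. An effect of G418 likewise cannot be told from one of UGT2B28 in the rescue libraries. The fits with knockdown library 3 alone, given below, were chosen after the result was seen and take their spread from the other groups.

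UGT2B28 mRNA did not pass as lower in the libraries labelled knockdown than in the controls. It was 12.6-fold higher in the rescue libraries than in those labelled knockdown. The gene lies on chromosome 4 at 69280499 to 69295050 on the plus strand (GRCh38). Its raw counts were 44, 50 and 76 in the control libraries, 63, 70 and 28 in the knockdown-labelled libraries and 1139, 1062 and 539 in the rescue libraries. In counts per 1000000 (CPM, scaled by TMM) this was 6.01 ± 1.55 (SD, n = 3) in control, 5.90 ± 2.73 (SD, n = 3) in knockdown-labelled and 73.8 ± 19.7 (SD, n = 3) in rescue libraries. The log2 fold change of knockdown-labelled against control libraries was -0.04 (SE 0.349, 95% confidence interval -0.81 to 0.72, edgeR adjusted p = 0.957). It was 3.66 for rescue against knockdown-labelled (SE 0.332, adjusted p = 0.00126, 95% confidence interval 2.93 to 4.39) and 3.61 for rescue against control (SE 0.329, adjusted p = 0.00267). That last p rose to 0.0599 without control replicate 1. The first change became 0.19 without control replicate 3 and 0.25 without knockdown replicate 3, still short of the threshold, and knockdown library 3 set alone against the controls gave -1.01 (adjusted p = 0.134). Because the counts do not bear out the label at the mRNA level, directions below are those of libraries labelled knockdown, not of cells shown to have less UGT2B28.

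Among the paralogs with counts, UGT2B11 was at 53.5 ± 10.2 CPM in control, 37.9 ± 6.14 in knockdown-labelled and 29.1 ± 9.10 in rescue libraries (SD, n = 3), and UGT2B15 at 5.03 ± 1.20, 7.36 ± 2.14 and 5.42 ± 0.845 CPM in the same order. Neither passed the test in any of the 3 comparisons. UGT2B4, UGT2B7 and UGT2B10 had 0 to 3 counts in each library, and UGT2B17 had 0 counts in all 9 libraries. Of the 1734 stretches of 100 bases in the UGT2B28 transcript, 5.71% occurred exactly in another gene, with 56 in each of the pseudogenes UGT2B24P and UGT2B25P and 17 in UGT2B11.

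**Figure D1:**
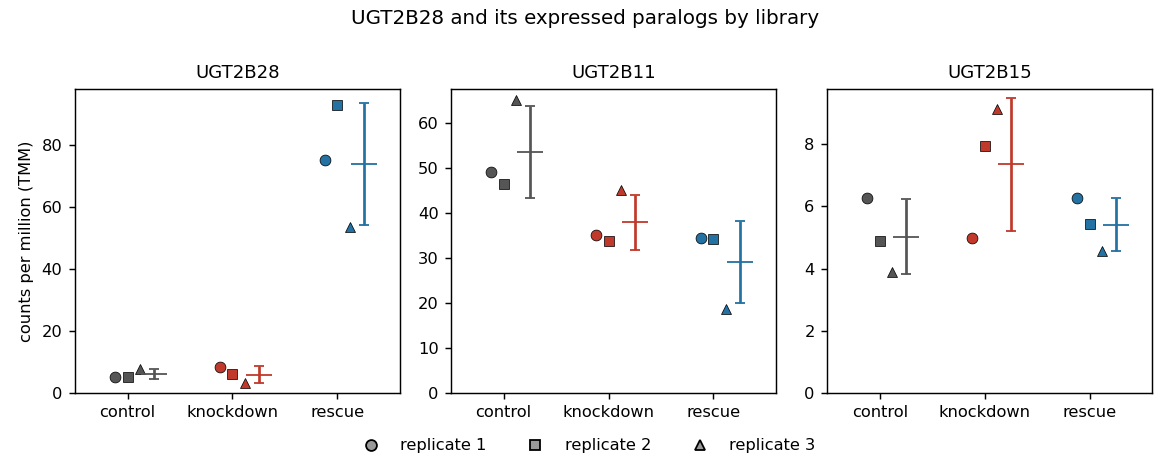
UGT2B28, UGT2B11 and UGT2B15 in counts per 1000000 after TMM scaling (vertical axes, each starting at 0) in the control, knockdown-labelled and rescue libraries. Each point is a library, shaped by replicate number, and the bars give the mean and SD of 3 libraries. UGT2B28 lay at 73.8 ± 19.7 CPM in the rescue libraries and near 6 CPM in both other groups.

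Knockdown libraries 1 and 2 resembled each other, and library 3 stood apart from them. Mitochondrially encoded transcripts took 15.1% and 15.8% of the counts in knockdown libraries 1 and 2 and 10.2% in library 3, against 7.62% to 8.57% in the controls. The cytosolic ribosomal protein mRNAs took 11.6%, 11.2% and 6.50% of the counts in knockdown libraries 1, 2 and 3. The chi-square per degree of freedom between the counts of 2 libraries was 3.57 for knockdown libraries 1 and 2, but 70.1 and 75.8 for each of them against library 3. It ran from 2.15 to 6.65 among the controls, so no pair of libraries lay within sampling noise and no duplicates were found.

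The comparison of knockdown-labelled with control libraries asks which transcripts shift when UGT2B28 is targeted. Of 16796 genes, 1 passed, the histone pseudogene H3P16 (chromosome 4, 139698144 to 139698554), which rose from 36.2 ± 1.16 to 75.5 ± 1.85 CPM (SD, n = 3; log2 fold change 1.06, SE 0.10, edgeR adjusted p = 0.00784). It is a processed pseudogene, so its reads may belong to near-identical H3 genes, and being the sole call it was named after its values were seen. No protein-coding gene passed, although 3209 genes had an unadjusted p under 0.05 and DESeq2 called 788.

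By group mean, mitochondrial, ribosomal and histone mRNAs were higher in the libraries labelled knockdown than in control, through libraries 1 and 2 and without a call at an estimated correlation. All 13 mitochondrially encoded mRNAs, which code for respiratory chain subunits, had a positive log2 fold change, with a median of 1.00 (camera adjusted p = 1.52e-07, and adjusted p = 0.950 with an estimated correlation). None of the 13 passed over all genes, and 12 passed adjusted over the list alone. MT-CO1 stood at 0.95 (adjusted p = 0.0970), MT-ND1 at 1.11 (adjusted p = 0.0970) and MT-ND4 at 1.28 (adjusted p = 0.0993). Of the 70 cytosolic ribosomal protein mRNAs, 69 were positive, with a median of 0.63 (camera adjusted p = 1.85e-08, and 0.950 with an estimated correlation) and 0 passing over all genes or adjusted over the list alone; RPS20 stood at 1.01, RPS4X at 0.70 and RPS3A at 0.91. Nuclear oxidative phosphorylation genes were positive in 34 of 39 cases, with a median of 0.54 (camera adjusted p = 0.00490, and 0.950 with an estimated correlation), including ATP5F1C at 0.71, NDUFB5 at 0.73 and COX6C at 0.91. The replication-dependent histone genes, whose mRNAs usually lack a poly(A) tail, were positive in 16 of 17 cases, with a median of 0.87 (camera adjusted p = 0.00647, and 0.950 with an estimated correlation), including H2AC6 at 0.90, H2BC12 at 1.17 and H1-2 at 1.91. The androgen-induced genes were positive in 34 of 52 cases, with a median of 0.25 (camera adjusted p = 0.0342, and 0.950 with an estimated correlation). PLPP1 stood at 0.57, ACSL3 at 0.48 and B2M at 1.05, and 3 of the 52 passed adjusted over the list alone. None of the members of these last 3 lists passed over all genes, and adjusted over the list alone 0 oxidative phosphorylation and 3 histone genes passed. The androgen-induced call was lost without control replicate 1 (camera adjusted p = 0.22) or 2 (0.210) and without knockdown replicate 1 (0.253) or 2 (0.168). Without scaling factors the median of the androgen-induced list was 0.0066, with 26 of 52 positive, and those of ribosomal proteins, oxidative phosphorylation and histones were 0.32, 0.22 and 0.57. Oxidative phosphorylation and histone calls were lost without knockdown replicate 1 (0.404 and 0.284) or 2 (0.114 and 0.0565).

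These group shifts belonged mainly to knockdown libraries 1 and 2. Relative to the control mean, the median over the mitochondrial mRNAs was 1.24, 1.28 and 0.26 in knockdown libraries 1, 2 and 3. It was 0.99, 0.91 and -0.30 for ribosomal proteins, 0.86, 0.82 and -0.39 for oxidative phosphorylation, 1.33, 1.04 and -0.17 for histones and 0.31, 0.44 and -0.04 for androgen-induced genes. The cell cycle list, with 26 of 49 positive and a median of 0.05, did not pass (camera adjusted p = 0.804), and neither did the steroid enzyme list (camera adjusted p = 0.388), in which STS stood at 1.27 (adjusted p = 0.109) and SULT2B1 at 0.77 (adjusted p = 0.158). The count of 1 gene became 5691 without knockdown replicate 3, 2115 without knockdown replicates 1 and 2, and 0 without any of the 3 controls or without knockdown replicate 1 or 2. Without scaling factors it was 153, 12 higher and 141 lower, and the median log2 fold change of all genes moved from 0.02 to -0.21.

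**Figure D2:**
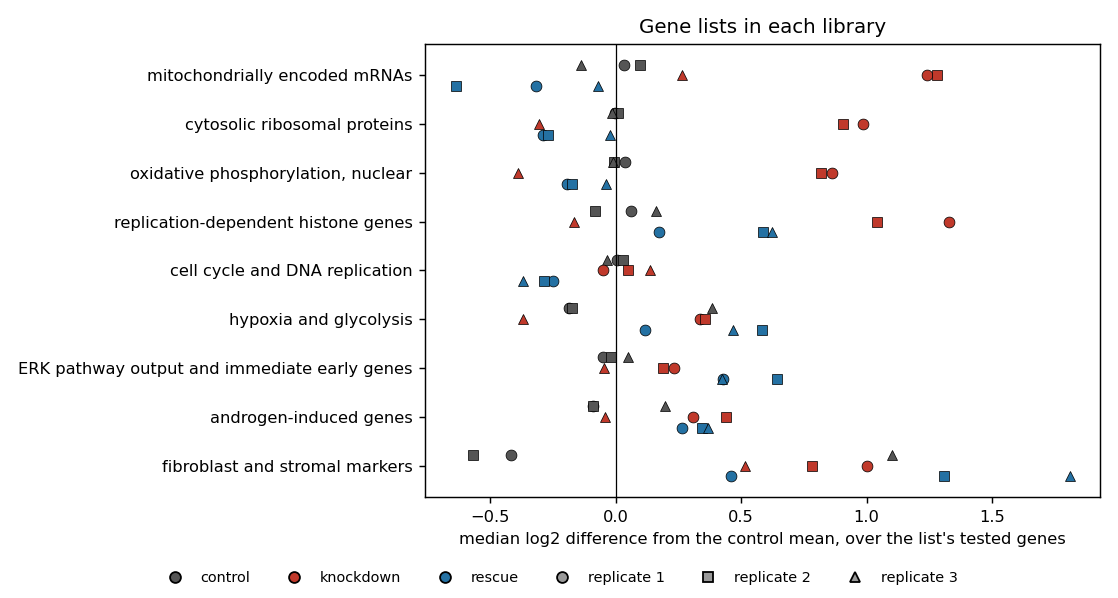
Median log2 difference from the mean of the control libraries (horizontal axis) over the tested genes of 9 gene lists (rows), one point per library, coloured by group and shaped by replicate number. Knockdown libraries 1 and 2 sit near 1 for mitochondrial, ribosomal protein and histone mRNAs while library 3 sits at 0.26, -0.30 and -0.17, and all 3 rescue libraries lie below 0 for the cell cycle list.

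The comparison of rescue with knockdown-labelled libraries asks what differs when UGT2B28 is overexpressed on the knockdown background. EGR1, MMP10 and CDH4 rose in the rescue libraries, and LTF, DEFB1, 11 of 13 mitochondrial mRNAs and 11 of 49 cell cycle genes fell. Of 16796 genes, 1651 passed, 745 higher and 906 lower in rescue, and 406 of them changed at least 2-fold. EGR1, an immediate early transcription factor induced by growth factor signalling, had the largest rise, from 0.562 ± 0.561 to 48.7 ± 43.2 CPM (SD, n = 3; log2 fold change 6.38, SE 0.751, adjusted p = 0.00605). Its rescue values were 23.9, 98.7 and 23.7 CPM. MMP10, a secreted matrix metalloproteinase, rose from 1.18 ± 0.307 to 15.6 ± 2.04 CPM (log2 fold change 3.71, SE 0.320, adjusted p = 0.00126), beside 3.66 for UGT2B28. The next rises were CNIH3 (3.21), the cadherin CDH4 (3.03), CDHR5 (2.71), the scaffold protein gene AKAP12 (2.64), SPATC1 (2.58), the phosphate transporter SLC34A3 (2.50) and the phosphofructokinase PFKP (2.48). LTF, which encodes lactoferrin, had the largest fall, from 15.1 ± 1.36 to 2.11 ± 1.07 CPM (log2 fold change -2.83, SE 0.410, adjusted p = 0.00866). It was followed by the beta-defensin DEFB1 (-1.86), SEBOX (-1.83), the epithelial transcription factor ELF5 (-1.51), ZNF492 (-1.49), MT-ND2 (-1.48), HHLA3 (-1.45), MT-ND4 (-1.44), BLOC1S1 (-1.41) and the myosin light chain kinase MYLK (-1.38).

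LTF and CDH4 set the libraries labelled knockdown apart from both other groups. Of all tested genes, 21.2% also did not overlap between knockdown-labelled and control libraries. LTF lay at 15.5, 16.2 and 13.6 CPM in the 3 knockdown-labelled libraries and at 2.32 ± 1.24 CPM in control, and CDH4 at 0.326 ± 0.307 CPM in knockdown-labelled against 2.15 ± 0.304 in control and 2.52 ± 0.822 in rescue (SD, n = 3). Against control neither passed, with adjusted p of 0.0602 for LTF (log2 fold change 2.70) and 0.0781 for CDH4 (-2.80).

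Of the 24 tested genes of ERK output and immediate early response, 5 rose and 0 fell, and 6 rose adjusted over the list alone; the median was 0.38 (camera adjusted p = 0.00158, and 0.813 with an estimated correlation). Without knockdown replicate 3 the camera adjusted p was 0.117, and without scaling factors the median was 0.67. Beside EGR1, the phosphatase gene DUSP4 rose by 0.94 and JUNB by 0.78 on the log2 scale. The medians of the list relative to the control mean were 0.23, 0.19 and -0.05 in knockdown libraries 1, 2 and 3 and 0.43, 0.64 and 0.42 in rescue. In the list of EGFR family members and regulators, 2 genes rose, EGFR (0.82) and its ubiquitin ligase CBL (0.54), and 2 fell, among them the sheddase ADAM17 (-0.48), with no shift of the list (camera adjusted p = 0.287). Of 49 cell cycle and DNA replication genes, 11 fell and 0 rose, and 16 fell adjusted over the list alone; the median was -0.30 (camera adjusted p = 1.36e-06, fry adjusted p = 0.01, and camera adjusted p = 0.355 with an estimated correlation). The replication clamp PCNA fell from 183 ± 6.83 to 103 ± 2.62 CPM (SD, n = 3; log2 fold change -0.82), CCNE2 had -0.81 and the mitotic kinesin KIF20A -0.88. Without scaling factors the median of the cell cycle list was -0.09, with 16 of 49 positive instead of 4.

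Transcripts for energy production and translation were lower in rescue, but this followed knockdown libraries 1 and 2. Of the 13 mitochondrial mRNAs, 11 fell and 0 rose, with a median of -1.35 (camera adjusted p = 2.82e-08, and 0.813 with an estimated correlation), among them MT-ND5 (-1.32), MT-CO1 (-1.20) and MT-CO2 (-1.37). Of 70 ribosomal protein mRNAs, 13 fell and 0 rose, with a median of -0.79 (camera adjusted p = 2.40e-11, and 0.836 with an estimated correlation), among them RPS20 (-1.24), RPS4X (-0.85) and RPS15 (-1.09). Of 39 nuclear oxidative phosphorylation genes, 6 fell and 0 rose, with a median of -0.72 (camera adjusted p = 5.12e-05, and 0.836 with an estimated correlation), among them NDUFB5 (-1.19), SDHD (-1.11) and ATP5F1C (-0.87). Adjusted over the list alone, 13, 48 and 8 members fell. Without scaling factors the medians were -1.03, -0.44 and -0.40. In knockdown library 3 the median relative to the control mean was 0.26 for mitochondrial mRNAs, above the rescue libraries (-0.32, -0.64 and -0.07), but -0.30 for ribosomal proteins, below them (-0.29, -0.27 and -0.02).

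Hypoxia and glycolysis genes rose in 5 of 36 cases and fell in 0, with a median of 0.24 (camera adjusted p = 0.00924, and adjusted p = 0.836 with an estimated correlation). The prolyl hydroxylase EGLN1 (1.41), PFKP (2.48) and PFKFB3 (1.19) led them. The call rested on knockdown library 3, and without scaling factors the median was 0.56. Relative to the control mean the list stood at 0.34, 0.35 and -0.37 in knockdown libraries 1, 2 and 3 and at 0.12, 0.58 and 0.47 in rescue. Its camera adjusted p was 0.990 without knockdown replicate 3, 0.0676 without rescue replicate 2 and 0.0528 without rescue replicate 3. Cholesterol and fatty acid synthesis genes rose in 5 of 34 cases and fell in 0, led by the sterol enzymes LSS (0.62) and CYP51A1 (1.53) and by LPIN1 (0.59), without a shift of the list (camera adjusted p = 0.287). Androgen-induced genes went both ways, with 4 of 52 higher and 1 lower (camera adjusted p = 0.109). RAB3B (1.11) and NDRG1 (1.18) rose and PLPP1 fell (-0.80). The clathrin endocytosis list held 2 rises, HIP1R (0.67) and EPN2 (0.46), and 1 fall, RAB11A (-0.51), among 33 genes (camera adjusted p = 0.636). Among the other UDP-glucuronosyltransferases and steroid enzymes, a list that leaves out UGT2B28, UGT8 alone of 16 passed over all genes (-1.18) and 0 passed adjusted over the list alone. TAGLN (0.83) passed alone among 25 mesenchymal genes and the interferon-induced MX1 (1.10) alone among 24 interferon-stimulated genes. Singly, the endoglin gene ENG (1.34), the ribosome biogenesis gene RRP12 (0.48) and EDEM1 (0.63), of protein quality control, rose. NPM1 (-0.68), SRM (-0.71), the surface glycoprotein gene CD24 (-0.75), PSAT1 (-0.47), the p53 targets CCNG1 (-0.60) and FBXO22 (-0.42), and the antioxidant genes TXN (-0.99) and NQO1 (-0.62) fell, and none of the lists holding these 11 genes passed.

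Only 7 genes passed when the knockdown-labelled and rescue libraries were fitted without the controls, and leaving out a library moved the count each time. It became 843, 802 and 1065 without control replicates 1, 2 and 3, 527, 226 and 6745 without knockdown replicates 1, 2 and 3, and 134, 284 and 280 without rescue replicates 1, 2 and 3. Without scaling factors 1557 genes passed, 1327 higher and 230 lower, and after a correction for gene length and GC content, chosen after the result was seen, 1342 passed, 359 higher and 983 lower.

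**Figure D3:**
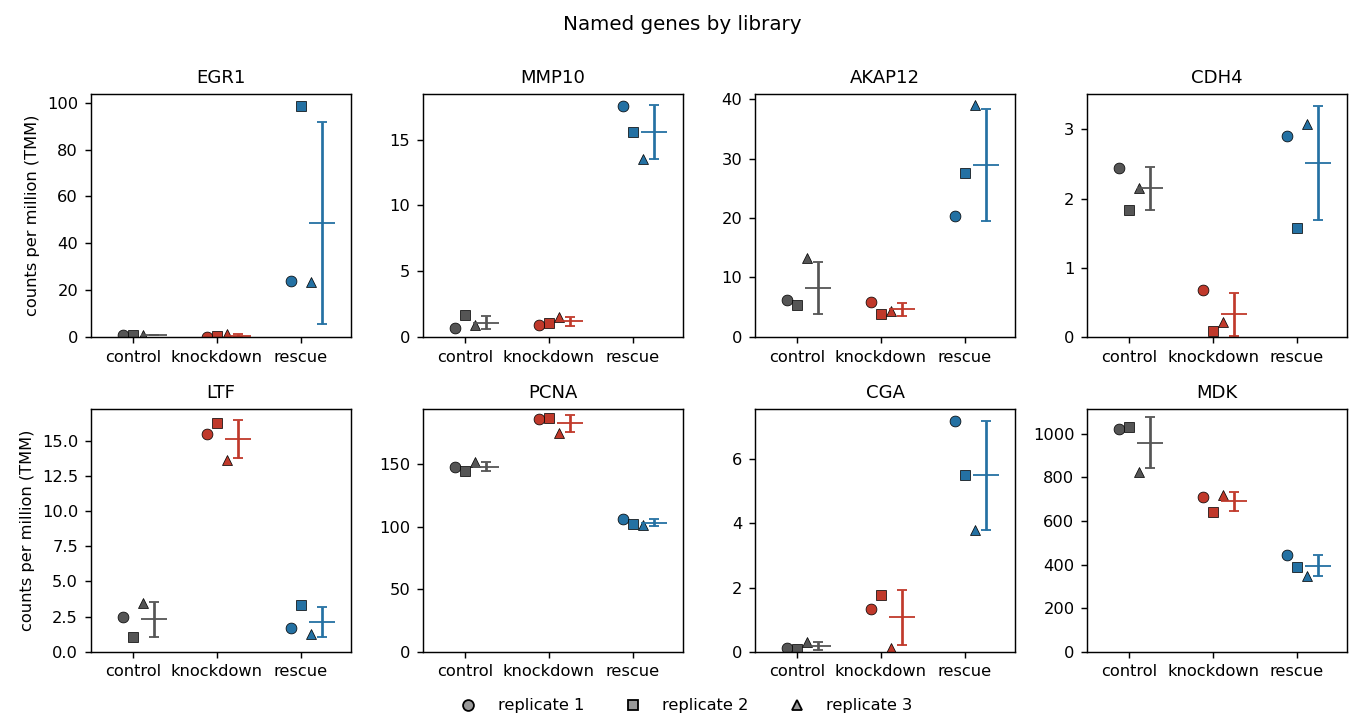
counts per 1000000 after TMM scaling (vertical axes, each starting at 0) of 8 named genes in the control, knockdown-labelled and rescue libraries. Points are libraries, shaped by replicate number, and bars give the mean and SD of 3 libraries. LTF at 15.1 CPM and CDH4 at 0.326 CPM separate the knockdown-labelled libraries from both other groups, whereas EGR1, MMP10, AKAP12, CGA, PCNA and MDK separate the rescue libraries.

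The comparison of rescue with control libraries asks how the rescue cells differed from the control cells, which were titled NT and also taken at day 30. Of 16796 genes, 25 passed, 24 higher and 1 lower in rescue. EGR1 (log2 fold change 6.07, SE 0.727, adjusted p = 0.0154) and MMP10 (3.82, SE 0.322, adjusted p = 0.00247) led with CGA, the common alpha subunit of the glycoprotein hormones, which rose from 0.175 ± 0.115 to 5.49 ± 1.70 CPM (SD, n = 3; log2 fold change 4.87, adjusted p = 0.0449). After UGT2B28 came the proteoglycan gene DCN (2.21), DOCK3 (2.15), the cadherin CDH6 (1.93), the SLIT receptor ROBO2 (1.74), the integrin activator FERMT2 (1.64) and the NF-kB-inducing kinase MAP3K14 (1.17). The fall was in MDK, which encodes the heparin-binding growth factor midkine and went from 960 ± 117 to 394 ± 47.6 CPM (SD, n = 3; log2 fold change -1.28, SE 0.151, adjusted p = 0.0154).

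By camera at the preset correlation, cell cycle genes were lower and androgen-induced and immediate early genes higher in rescue than in control, and none of the 3 calls held at an estimated correlation. All 49 cell cycle genes had a negative log2 fold change, with a median of -0.29 (camera adjusted p = 5.35e-12, fry adjusted p = 0.00832, and camera adjusted p = 0.0754 with an estimated correlation), although none passed over all genes and 1 passed adjusted over the list alone. PCNA stood at -0.52 (adjusted p = 0.0759), MCM5 at -0.47 and MCM3 at -0.48. Of 52 androgen-induced genes, 46 were positive, with a median of 0.34 (camera adjusted p = 9.32e-09, and 0.439 with an estimated correlation). None passed over all genes and 10 passed adjusted over the list alone. The elongation factor ELL2 stood at 0.71 (adjusted p = 0.0752), INPP4B at 0.88 and NNMT at 1.09. Of the 24 ERK output and immediate early genes, 21 were positive, with a median of 0.60 (camera adjusted p = 7.27e-09, fry adjusted p = 0.0488, and camera adjusted p = 0.289 with an estimated correlation). Only EGR1 of them passed over all genes and 10 passed adjusted over the list alone; EPHA4 stood at 1.15 (adjusted p = 0.0636) and FOSB at 2.98 (adjusted p = 0.0701). Both of these genes passed against the knockdown-labelled libraries, EPHA4 at 0.79 and FOSB at 2.26.

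Hypoxia and glycolysis genes were positive in 35 of 36 cases, with a median of 0.38 (camera adjusted p = 4.21e-07, and adjusted p = 0.623 with an estimated correlation), including PFKP at 2.44, HK2 at 0.66 and CA12 at 1.60. None of the 36 passed over all genes and 3 passed adjusted over the list alone. Controls 1, 2 and 3 stood at -0.19, -0.18 and 0.38 for this list, so control 3 lay within the rescue range of 0.12 to 0.58. Of 11 fibroblast and stromal markers, 10 were positive, with a median of 1.21 (camera adjusted p = 3.79e-05, and adjusted p = 0.439 with an estimated correlation). DCN passed over all genes and 2 members adjusted over the list alone. LUM stood at 2.32 (adjusted p = 0.0793) and COL6A1 at 0.37. The median of this list, relative to the control mean, was -0.42, -0.57 and 1.10 in controls 1, 2 and 3 and 0.46, 1.31 and 1.81 in the rescue libraries, so control 3 lay within the rescue range. Mesenchymal genes had a median of 0.40 (camera adjusted p = 0.00643, and adjusted p = 0.508 with an estimated correlation; 0.0943 by camera without rescue replicate 3). Control 3 stood at 0.29 for these genes, against -0.13 and -0.16 in controls 1 and 2, and the rescue libraries at 0.09, 0.38 and 0.68. Fibronectin, FN1, passed (0.92), and adjusted over the list alone 2 genes rose and 1 fell. TAGLN stood at 0.58 and CDH11 at -1.96. By camera 6 more lists passed: antigen presentation (median 0.46, adjusted p = 0.0103), cholesterol synthesis (0.12, 0.00550) and histones (0.38, 0.00617) were higher, and ribosomal proteins (-0.18, 0.00550), mitochondrial mRNAs (-0.29, 0.0182) and oxidative phosphorylation (-0.16, 0.0256) lower. With an estimated correlation their adjusted p was 0.480, 0.623, 0.675, 0.773, 0.729 and 0.754 in that order. Each of these 6 calls was lost by camera without some library. The adjusted p reached 0.0597 for antigen presentation without control replicate 1, 0.0840 for cholesterol synthesis without rescue replicate 2, and 0.110 for ribosomal proteins without rescue replicate 1. It reached 0.0597 and 0.0850 for histones without control replicate 3 or rescue replicate 2. Mitochondrial mRNAs reached 0.0551 and 0.0832 without control replicate 1 or 2 and 0.0585 and 0.241 without rescue replicate 1 or 2. Oxidative phosphorylation reached 0.0558 without control replicate 1 and 0.110 and 0.0620 without rescue replicate 1 or 2. Endothelial markers did not pass (camera adjusted p = 0.178), and only 2 of the 20 immune cell markers were measured well enough to be tested. The EGFR gene stood at 0.68 (adjusted p = 0.108) and CBL at 0.47 (adjusted p = 0.151).

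Leaving out any of the 9 libraries moved the count of 25 genes by more than 1.5 times. It became 1, 3 and 11 without control replicates 1, 2 and 3, 12, 12 and 1276 without knockdown replicates 1, 2 and 3, and 3, 4 and 5 without rescue replicates 1, 2 and 3. Fitted without the knockdown-labelled libraries, rescue and control differed in 962 genes, 642 higher and 320 lower.

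For the genes changed in knockdown-labelled libraries and changed back in rescue, the overlap of the calls was H3P16 alone, which fell to 30.3 ± 0.0931 CPM in rescue (SD, n = 3; log2 fold change -1.32, adjusted p = 0.000886), a recovery of 124%. In simulated counts the recovery had a median of 15.0% over 20 runs with no rescue. With no effect at all its median was 85.6% (82.6% to 88.6%). That value rests only on those of the 20 runs that called a gene in the first comparison, a number not recorded. The runs with no rescue gave a median of 0 reversed genes, from 0 to 2. Independent lists of these sizes would share 0.0539 genes. Across genes, which are not independent replicates, the fold changes of the first and second comparisons had a correlation of -0.675, against -0.297 in the simulation with no rescue and -0.506 in that with no effect at all. Their covariance was -0.196 against -0.0588 and -0.0585 in the simulations, while the spread among the knockdown-labelled libraries by itself gives -0.108. The simulations thus understate the spread that both comparisons share, so a value beyond the simulated ones does not show a reversal. Part of the correlation may therefore come from the knockdown-labelled libraries that both comparisons share, and 3 libraries cannot be split with 2 in each part to test it.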

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

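The sample quality weights, the fit without both knockdown replicates 1 and 2 and the correction for length and GC content were chosen after seeing the data; the other alternatives were not. The rise of UGT2B28 in rescue against knockdown-labelled libraries kept its direction and passed in every alternative run; that against control kept its direction but missed the threshold without control replicate 1 (adjusted p = 0.0599). Its change between knockdown-labelled and control libraries passed in none. That change was -0.33 with library size alone and -0.21 after length and GC correction, and turned positive with quality weights (0.26). It ran from -0.36 to 0.25 with each library left out, being 0.19 without control replicate 3 and 0.25 without knockdown replicate 3. The counts of genes depended on the settings throughout, and except where fewer libraries or genes were fitted the cause was not tested.

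For knockdown-labelled against control, the count of 1 became 153 with library size alone, 1045 without a filter, 788 in DESeq2, 6527 with quality weights, 2115 without both knockdown replicates 1 and 2, 2 after length and GC correction and 0 with only the groups compared; with each library left out it ran from 0 to 5691. For rescue against knockdown-labelled, the count of 1651 became 2636 without a filter, 7 with only the groups compared, 6999 with quality weights, 3619 without both knockdown replicates 1 and 2, 406 at a 2-fold change and 162 at an adjusted p under 0.01, and ran from 134 to 6745 with each library left out. For rescue against control, the count of 25 became 401 without a filter, 267 in DESeq2, 13 in limma-voom, 962 with only the groups compared, 1590 with quality weights, 977 without both knockdown replicates 1 and 2, 14 at a 2-fold change and 3 at an adjusted p under 0.01, and ran from 1 to 1276 with each library left out. Quality weights gave knockdown library 3 a weight of 0.107, the lowest of the 9.

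The overlap of 1 reversed gene became 142 with library size alone, 768 without a filter, 593 in DESeq2, 4799 with quality weights, 1716 without both knockdown replicates 1 and 2, 2 after length and GC correction and 0 with only the groups compared, and ran from 0 to 4490 with each library left out. The share recovered, 124% for H3P16 alone, is in the alternatives a median over whichever genes were called there, so it does not follow that gene. It became 105.2% with library size alone and also without a filter, 101.3% in DESeq2, 101.2% with quality weights, 95.8% without both knockdown replicates 1 and 2 and 138.5% after length and GC correction, and ran from 102.7% to 124.7% with each library left out. It had no value in the 7 alternatives that called no gene.

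The 5, 6 and 12 lists called in the 3 comparisons became 0 in each with an estimated correlation. With fry they became 0, 1 and 2. Without both knockdown replicates 1 and 2, the first became 3 and the second 10, and with each library left out the first ran from 2 to 7. Those 3 kept none of the original 5 calls. Ribosomal proteins and oxidative phosphorylation turned from higher to lower against control, and hypoxia and glycolysis was newly called, as lower. The mitochondrial, histone and androgen-induced calls were lost. Among the 10, ribosomal proteins turned from lower to higher in rescue, and oxidative phosphorylation was no longer called.

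Replicate numbers did not pair the libraries: correlations of same-numbered deviations ran from -0.355 to 0.0784, and rescue library 3 correlated at 0.269 with knockdown library 1 but at -0.355 with number 3. With the replicate block the counts became 0, 442 and 4, and the overlap of reversed genes became 0.

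Of the 53 named genes that passed for rescue against knockdown-labelled, 13 passed with each library left out, 3 with only the groups compared, 40 without both knockdown replicates 1 and 2 and all 53 in DESeq2. Of the 12 for rescue against control, 1 passed with each library left out and all 12 with only the groups compared. Signs turned without both knockdown replicates 1 and 2 for RPS3A (-0.01), COX6C (-0.10), H2BC12 (-0.058), H1-2 (-0.60) and SULT2B1 (-0.0079) against control, and for UGT2B15 in rescue against control (-0.0402 without control replicate 3, -0.0058 without rescue replicate 1, and up to 0.3018 without control replicate 1). Depth limits low genes most: CDH4 had 1 to 5 counts per knockdown-labelled library.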

Other observations

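The tests of mislabelling, of UGT2B11 reads and of too few counts, and the comparison of fits without parts of the knockdown-labelled group, were chosen after the results were seen.

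LTF and CDH4, picked after their values were seen, separated all 3 knockdown-labelled libraries from both other groups. Of 16796 genes, 21.2% did not overlap between knockdown-labelled and control libraries and 28.6% between rescue and knockdown-labelled, against 10% by chance. LTF had a log2 fold change against control of 2.77 from knockdown libraries 1 and 2 and of 2.52 from library 3 alone, and CDH4 of -2.64 and -3.25. Against control, 5677 genes passed without knockdown library 3 and 2097 with library 3 alone, of 17263 tested in both fits. Of the 972 that passed in both, 316 changed in the same direction and 656 in opposite directions, where independent lists of these sizes would give 324.3 and 365.3 and simulations with no effect gave a median of 0 for each. The simulated 0 is no measure of either overlap, since few genes pass at all when no effect is simulated. The fold changes of these fits had a correlation across genes of 0.0111, although shared controls with no effect gave a median of 0.294 over 20 simulations. Their covariance was 0.00674 against 0.0621 simulated. Of the 316, 209 also passed the opposite way in rescue against knockdown-labelled libraries, 60 of them higher and 149 lower in the latter, a number raised by the libraries these fits share.

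Of the 25 genes that passed for rescue against control, 18 had a mean between the 2 in the libraries labelled knockdown and 7 did not, and none of the 18 passed for knockdown-labelled against control. A gene with a wide gap between rescue and control falls between easily, so this tally is not a test. The examples that follow were picked for their order. DCN was at 2.80 ± 0.616, 9.26 ± 3.81 and 12.98 ± 0.820 CPM in control, knockdown-labelled and rescue libraries (SD, n = 3). CDH6 was at 6.07 ± 1.30, 14.2 ± 2.01 and 22.9 ± 7.46 CPM, ROBO2 at 3.19 ± 0.849, 8.11 ± 1.37 and 10.7 ± 1.51 CPM, and MDK at 960 ± 117, 692 ± 43.6 and 394 ± 47.6 CPM. UGT2B28, at 6.01, 5.90 and 73.8 CPM, EGR1, at 0.715, 0.562 and 48.7 CPM, and MAP3K14, at 37.4, 32.1 and 84.1 CPM, were among the 7 that did not follow that order.

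Knockdown libraries 1 and 2 stood apart from library 3. A rescue library under a wrong label is excluded, since UGT2B28 in library 3 was 5.69% of that in the lowest rescue library. For a control culture under a wrong label, the distance of library 3 to its nearest control was 3.28 times the largest between controls. By chi-square per degree of freedom, however, library 3 lay nearer to the controls (21.8 to 23.6) than to knockdown libraries 1 and 2 (70.1 and 75.8). This distance therefore cannot settle the label of library 3. The ribosomal protein list was 1.30 and 1.23 higher in libraries 1 and 2 than in library 3. This lay above the middle 95% of 10000 length-matched lists, which ended at 0.35 and 0.33. Length here is that of all annotated exons of a gene together, which can exceed that of its mRNA. The matched lists may therefore hold longer mRNAs, and gene length bias stays open. Separate cultures, clones or preparations stay open, because the labels name none, and no biological explanation was tested. A wrong label of libraries 1 and 2 was not tested.

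UGT2B28 did not pass as lower in the libraries labelled knockdown. Reads of UGT2B11 counted as UGT2B28 stay open. Such reads would give both genes the same fold change, and the log2 fold change of UGT2B28 exceeded that of UGT2B11 by 0.454 (SE 0.419), within its error, while the ratio of the counts ran from 6.78% to 24.2% over 6 libraries. Only 17 of 1734 windows were identical, which counts against identical sequence as the source but does not cover reads misplaced between near-identical stretches. After TMM scaling, the lower bound of the interval, -0.8139, lay above -1. This argues against too few counts to see a halving in the group under that scaling. With library size alone the log2 fold change was -0.33 and no interval was computed, and library 3 alone stood at -1.01. A knockdown lost by day 30, or one that acts below the mRNA level, was not tested and stays open.

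Rescue against knockdown-labelled libraries called 1651 genes and rescue against control 25. This excess kept its direction with each library left out in turn. With only the 2 groups compared, however, the counts were 7 and 962, the reverse order, although 1648 of the 1651 genes kept their direction. The joint fit takes its spread from all 3 groups together. The chi-square per degree of freedom within a group reached 75.8 in knockdown-labelled, 10.7 in rescue and 6.65 in control libraries. The counts thus depend on which libraries supply the spread, and the excess does not show a larger difference. The part of this pooling in the reversal was not tested separately. After the length and GC correction 1342 genes passed, but only 801 of the original 1651 (48.5%) were among them in the same direction. The calls became 359 higher and 983 lower, from 745 and 906, so the correction moved the balance of directions. A similar total reached with other genes cannot decide the question, and length and GC bias stays open. Whether the unusual knockdown libraries 1 and 2 produce the excess cannot be told apart from a change common to the group: 53.6% of the 1651 genes passed the same way against library 3 alone, where a lone library is assumed to vary like the other groups.

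The 10 splits of 6 libraries into 3 and 3 are too few for a share under 0.05. For knockdown-labelled against control, the real split called 1 gene and the highest other split 89, so 2 of 10 reached the real count; the 89 came from placing knockdown library 3 with controls 1 and 2. For rescue against knockdown-labelled, 1 of 10 splits, the real one, reached 1651, and the highest other called 1232, with rescue library 3 placed beside knockdown libraries 1 and 2. For rescue against control, 1 of 10 reached 25, and the highest other called 0. The splits with 89 and 1232 genes point to a structure of the libraries that their groups do not describe.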
